A study of Homo sapiens with 4 samples.

How the data were processed

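The study measured gene expression in cultured primary normal human epidermal keratinocytes (NHEK), the main cell type of the epidermis, on 4 Affymetrix GeneChip microarrays. Per the labels, the cells grew in a serum-free medium with 0.06 mM calcium and received vehicle or 10 µM adenosine. The groups were vehicle (2 arrays) and adenosine (2 arrays), taken from the sample titles. The titles also carry the numbers 1 and 2. Nothing in the labels says whether a number stands for a donor, a culture or a day. The p-values of single genes therefore measure only the spread between these arrays, which can be technical. The length of the exposure, the array model and the versions of the authors' software are not given in the sources used here.

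The authors deposited log2 expression values, 1 per probe set and array, for 22277 probe sets. Per the submitters' processing notes, RMA and the affy package were named for this step. RMA corrects the background, normalizes quantiles across arrays and summarizes the probes of a set on the log2 scale, which makes the arrays alike in overall distribution and removes any global shift between them. The array medians of the deposited log2 values were 8.18 and 8.20 (vehicle arrays 1 and 2) and 8.19 and 8.17 (adenosine arrays 1 and 2), and the values ran from 3.29 to 15.6. The value table of the series held the same values in another row order, with a largest difference of 5e-09. No detection calls or scanner values were used here, so a dim probe set cannot be called undetected. The number of arrays, not a read depth, limits the precision.

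Probe sets were named from GEO's platform annotation, and symbols were updated through Entrez identifiers to the gene table of a current human annotation. The 62 control probe sets were left out. Of the other 22215 probe sets, 19065 had 1 gene, 1043 had several and 2107 were unnamed here. Symbols of 19053 of the 19065 were matched by identifier and the rest kept the name of the annotation. No genome build is named for the arrays, so no coordinates are given. Genes were represented by their brightest probe set over all 4 arrays, which gave 11963 genes, of which 4310 had more than 1 probe set.

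Each gene was tested with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided) in a fit of all 4 arrays with treatment as the only term. Differences are adenosine minus vehicle on the log2 scale, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior with 4.42 degrees of freedom. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so none was used as a main test. Groups of genes were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over 22 lists. With this setting camera compares a list's genes with the other genes, and its p does not measure how the list's mean varies between arrays. A difference between arrays unrelated to adenosine can therefore give a small p. The lists held 449 entries, of which 378 were measured under a single gene name. The other 71 are not analysed here. Beside camera stand its version with an estimated correlation and fry, whose main p tests whether a list's genes move, on balance, one way. fry's mixed p tests change in either direction. Both p-values of fry rest on the spread between arrays, which can be technical. Members that pass when adjusted over their list alone are also named. That adjustment was not part of the design fixed in advance and does not correct over the 22 lists. Passing it is a description of the list, and such genes did not pass over all genes.

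The design, the lists and the rule for the genes named were fixed before the data were examined. The rule names up to 12 rises and 12 falls among genes past the threshold. With fewer, it names the 8 genes per direction with the smallest p among those whose arrays did not overlap between groups. It also names the 2 members of each list with the smallest p, and the adenosine receptors. Genes named outside it in the report are marked as chosen after their values were seen, and all genes named from lists added later were chosen in that way. Alternatives were the title number as a block, no dim genes, the mean of a gene's probe sets, centring, quantile normalization again, the series value table, an intensity trend or robust prior in eBayes, a threshold of 0.10, single probe sets, leaving out each array in turn, and the other list tests. Leaving out an array leaves a group with 1 array, which was assumed to vary like the other group.

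The fits were tested on simulated data with 2 arrays per group and 20 simulations of 200 changed genes. The data used the means of the 11963 genes and variances drawn at random from limma's fitted prior, not each gene's own variance. The changed genes were split equally over changes of 0.5, 1, 2 and 4 on the log2 scale. limma recovered 49.5% of genes changed by 0.5, 95.9% of those changed by 1 and 99.7% of those changed by 2. There were 9.35 false calls per simulation. The many large changes ease the adjusted threshold for the small ones. In the real data 1 gene differed by 1 or more, so the recovery of small changes there was not measured and can be lower. For lists of 25 independent genes shifted by 0.2, camera with the preset correlation recovered 100% and called 0% of unshifted lists. With a true correlation of 0.3 within lists, it called 27.5% of unshifted lists. camera with an estimated correlation recovered 0% of the lists shifted by 0.2 or 0.4, so a call it loses at this sample size says little about the list.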

Results

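The response of keratinocytes to extracellular adenosine was measured by comparing 2 arrays of cells given 10 µM adenosine with 2 arrays of cells given vehicle. The 4 arrays were alike. Across 11963 genes the correlation was 0.9982 between the vehicle arrays and 0.9980 between the adenosine arrays. Between groups it was 0.9985 for vehicle array 1 with adenosine array 1, 0.9979 for vehicle array 1 with adenosine array 2, 0.9979 for vehicle array 2 with adenosine array 1 and 0.9975 for vehicle array 2 with adenosine array 2. The median absolute difference was 0.091 (log2) between the vehicle arrays, 0.090 between the adenosine arrays and 0.062 between the group means. Means of 2 arrays vary less than single arrays, so the last value does not show that the groups were closer than replicates. Adenosine array 2 stood apart in 1 of 2 signs of RNA quality: its 3' minus 5' difference for the beta-actin control probe sets was 1.47, against 0.90 on adenosine array 1 and 1.04 and 0.89 on the vehicle arrays. For GAPDH the difference was 0.28 on adenosine array 2, 0.17 on adenosine array 1, and 0.16 and 0.25 on the vehicle arrays, so that array did not stand apart there. The mean of the 18S ribosomal RNA control probe sets was 14.1 and 14.0 on the vehicle arrays, and 13.9 and 13.7 on the adenosine arrays.

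No single gene passed the threshold with adenosine, and differences were small. By limma with Benjamini-Hochberg adjustment, 0 of 11963 genes had an adjusted p under 0.05 and the smallest adjusted p was 0.718. At an unadjusted p under 0.05 there were 630 genes, 368 with a positive and 262 with a negative difference, against 598 expected with no effect. The split was 332 positive and 297 negative with arrays centred on their medians, and 353 and 339 after quantile normalization again. The arrays of the groups did not overlap for 33.0% of genes, and chance gives 33.3%. The difference was 0.5 or more in size for 28 genes, 23 positive and 5 negative, and reached 1 for a single gene, IFITM1, an interferon-induced membrane protein named after its values were seen. IFITM1 was at 8.74 ± 0.49 with vehicle and 9.75 ± 0.33 with adenosine (SD, n = 2), and its sequence is close to that of related IFITM genes.

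The genes of smallest p with a positive difference included an epithelial surface protein, a growth factor receptor and an aldo-keto reductase. LY6D, a surface protein of the Ly6 family, was at 9.34 ± 0.026 with vehicle and 10.09 ± 0.26 with adenosine (SD, n = 2), a fold of 1.68. AKR1B10, an aldo-keto reductase, was at 8.57 ± 0.033 and 9.26 ± 0.18, a fold of 1.62. FGFR3, a fibroblast growth factor receptor, had a fold of 1.53, and its probe sets gave differences from 0.11 to 0.61. The folds were 1.61 for the interferon-induced IFI6, 1.46 for CYFIP2, a component of the actin-regulating WAVE complex, 1.33 for the cobalamin-binding protein TCN1, 1.34 for CCDC85B and 1.34 for the zinc finger gene ZNF254. With a negative difference, SLC7A11, the cystine transporter subunit, was at 11.49 ± 0.044 with vehicle and 10.92 ± 0.050 with adenosine, a fold of 0.676, and all 3 of its probe sets were lower. AGR2, a protein disulfide isomerase of the endoplasmic reticulum, had a fold of 0.676, the secreted glycoprotein STC2 0.711, the annexin ANXA6 0.731, DEPP1 0.727, the cytokine TNF 0.727, the chemokine CCL20 0.722 and asparagine synthetase (ASNS) 0.750. Probe sets of a gene differed in size for CYFIP2 (log2 differences from 0.20 to 0.54), CCDC85B (0.13 to 0.42) and DEPP1 (-0.46 to -0.082), and the brightest gave the values above. All 16 of these genes had an adjusted p of 0.718 by limma, so none was called once all genes were counted. With 2 arrays per group, this does not show that they were unchanged.

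**Figure D1:**
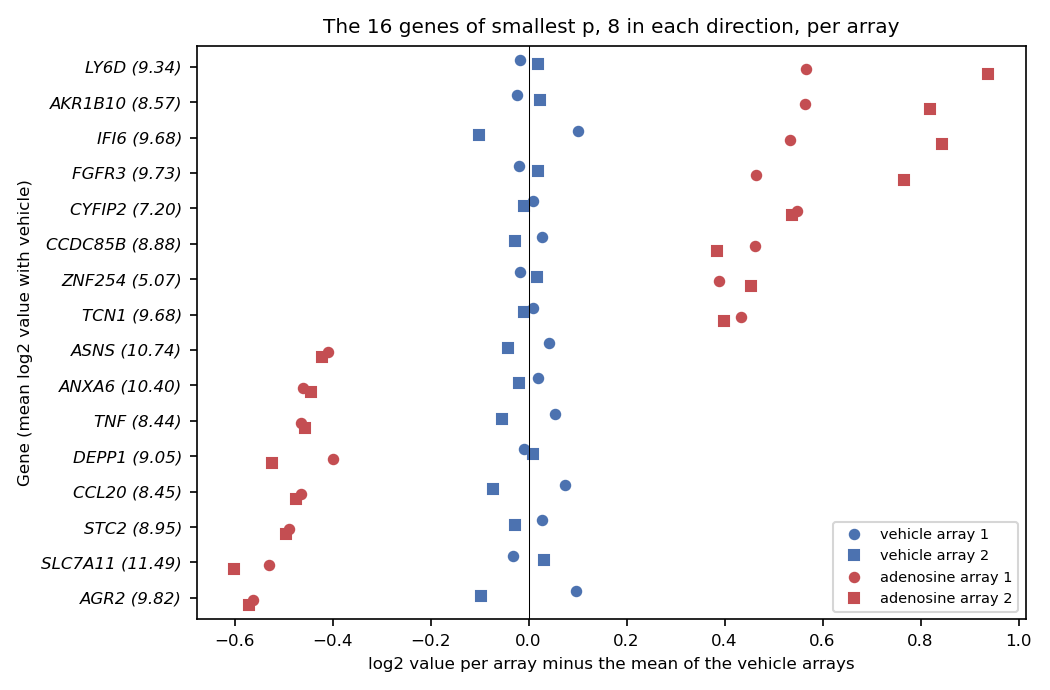
Log2 value of each array minus the mean of the vehicle arrays, for the 16 genes of smallest p (8 in each direction) among those whose groups did not overlap; blue points are vehicle, red points adenosine, circles array 1 and squares array 2. The separation of red from blue is part of how the genes were chosen, and no gene had an adjusted p below 0.718.

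By camera with the preset correlation, groups of genes gave calls where single genes gave none. Of the 22 lists, 7 passed camera's threshold with the preset correlation, 2 higher (type I interferon, antimicrobial genes and wound keratins) and 5 lower (ATF4 and unfolded protein response, TGF-beta and matrix, cytokines and chemokines, EGFR ligands and ERK feedback, cholesterol synthesis). None passed with an estimated correlation, and none passed fry. The estimated correlations were 0.38 (interferon), 0.50 (TGF-beta), 0.22 (EGFR), 0.19 (cytokines) and 0.12 (antimicrobial), against the preset 0.01. They were nearer to it for ATF4 (-0.023) and cholesterol synthesis (0.023). All were estimated with 2 residual degrees of freedom, so they are too imprecise to rank the lists. The ATF4 call was lost although its estimate lay below 0.01, so a lost call need not reflect correlated genes. camera with an estimated correlation recovered 0% of shifted lists in the simulation, also where genes were independent. In the simulation the preset test called 27.5% of unshifted lists at a true correlation of 0.3. Its p-values for lists with correlated genes can therefore be too small. fry's mixed test, for change in either direction, called 6 lists: ATF4 and unfolded protein response, cytokines and chemokines, NF-kB feedback, cAMP and CREB targets, NRF2 targets, and cholesterol synthesis. The 2 lists whose camera calls held when each array was left out in turn were type I interferon and ATF4 and unfolded protein response.

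**Figure D2:**
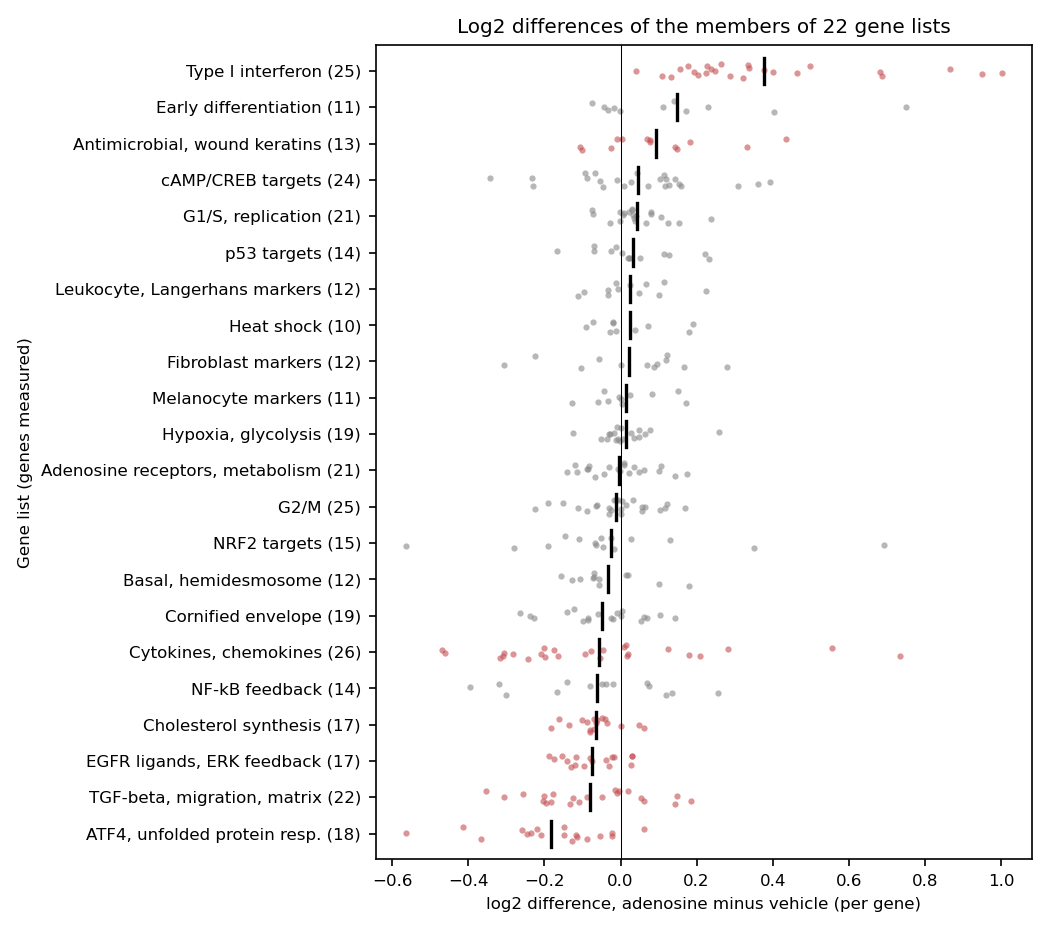
Log2 difference (adenosine minus vehicle) of each measured member of the 22 lists, with the number of members in parentheses; black bars are list means, and red marks the 7 lists past camera's threshold with the preset correlation. All 25 interferon genes lie above 0 and 17 of 18 ATF4 and unfolded protein response genes lie below it.

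The list of genes induced by type I interferon was higher with adenosine by camera with the preset correlation, and not by its other tests. All 25 measured members had a positive difference, with a mean of 0.38 (a fold of 1.30) and a median of 0.29, and the groups did not overlap for 20 of them. IFI6 was at 9.68 ± 0.14 with vehicle and 10.37 ± 0.22 with adenosine (SD, n = 2), and HERC5, the ligase that attaches ISG15 to proteins, at 8.34 ± 0.14 and 8.80 ± 0.087, a fold of 1.38. IFIT1 (0.95) and MX1 (0.87), antiviral effectors named after their values were seen, had the largest differences of the list after IFITM1. Over all genes 0 members passed, and adjusted over the list alone 12 did, all positive. The adjustment over the list alone does not correct for the other lists. camera's adjusted p was 1.42e-19 with the preset correlation and the adjusted p = 0.762 with an estimated correlation, and fry's adjusted p was 0.551. The list also varied within groups: its mean was 8.12 and 7.93 on the vehicle arrays, and 8.32 and 8.50 on the adenosine arrays, of which the last was the array with the higher beta-actin 3' to 5' difference. Without adenosine array 2 the mean difference was 0.29, and leaving out each array gave 0.28 to 0.47.

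The list of ATF4 and unfolded protein response genes was lower with adenosine by camera with the preset correlation, and not by camera with an estimated correlation or by fry's main test. Of 18 measured members, 17 had a negative difference, with a mean of -0.18 (a fold of 0.881) and a median of -0.15, and the groups did not overlap for 10 of those 17. SLC7A11 and ASNS, both described above, led the list, followed by the endoplasmic reticulum chaperone HYOU1 (-0.37, named after its values were seen). These 3 genes passed when adjusted over the list alone, and 0 members passed over all genes. camera's adjusted p was 7.67e-10 with the preset correlation and the adjusted p = 0.429 with an estimated correlation, and fry's adjusted p was 0.152 (0.0161 in its mixed test, which has no direction). The array means of this list were close within groups, at 11.29 and 11.30 with vehicle and 11.10 and 11.12 with adenosine. Leaving out each array gave mean differences from -0.19 to -0.17.

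Cytokine and chemokine genes went both ways, with a balance towards lower values. Of 26 members, 16 had a negative and 10 a positive difference, with a mean of -0.056 and a median of -0.086. TNF (-0.46, SE 0.077) and CCL20, a chemokine for cells bearing CCR6 (-0.47, SE 0.082), had the smallest p. Both, at 8.44 and 8.45 with vehicle, were among the genes dropped when dim genes were left out. Adjusted over the list alone, TNF, CCL20, LIF (-0.32) and IL1A (-0.28) passed with a negative difference, and the chemokine CXCL14 (0.74) and the alarmin IL33 (0.55) with a positive one. LIF, IL1A, CXCL14 and IL33 were named after their values were seen, and 0 members passed over all genes. camera's adjusted p for the list was 0.00736, and the adjusted p = 0.859 with an estimated correlation. The call was lost without vehicle array 1 (adjusted p 0.191, mean -0.014), without adenosine array 2 (adjusted p 0.261, mean -0.022) and without dim genes (adjusted p 0.311, mean -0.016). The mean was -0.098 without vehicle array 2 and -0.090 without adenosine array 1, and the adjusted p ran from 0.00167 to 0.859 over 13 alternatives. The NF-kB feedback list did not pass camera (14 members, mean -0.061, adjusted p 0.0862). Its mean was -0.091 without vehicle array 1 (adjusted p 0.0319), -0.031 without vehicle array 2 (adjusted p 0.358), -0.036 without adenosine array 1 (adjusted p 0.526) and -0.13 without dim genes (adjusted p 0.00493), with a range of adjusted p from 0.00493 to 0.859 over 13 alternatives. fry's mixed test gave an adjusted p of 0.0339. Its member TNFAIP3, an inhibitor of NF-kB, was at 12.28 with vehicle and 11.88 with adenosine and passed adjusted over the list alone; the surface protein CD83 had a difference of -0.32.

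Lists of growth factor signalling and matrix genes were lower with adenosine, but each call was lost when a single array was left out. In the TGF-beta, migration and matrix list, 16 of 22 members had a negative difference (mean -0.082), among them the gelatinase MMP9 (-0.35, SE 0.074) and the activin subunit INHBA (-0.31, SE 0.082; -0.088 on its other probe set). Its camera adjusted p was 0.00320, and the adjusted p = 0.907 with an estimated correlation. In the EGFR ligand and ERK feedback list, 14 of 17 were negative (mean -0.076), among them the ligand EREG (-0.18, SE 0.081) and the ERK phosphatase DUSP6 (-0.14, SE 0.083). Its adjusted p was 0.00736, and the adjusted p = 0.859 with an estimated correlation. Without adenosine array 2 EREG was at -0.11 and DUSP6 at -0.079. Neither list had a member past the threshold over all genes or adjusted over the list alone. Without vehicle array 2 the mean differences were -0.015 (adjusted p 0.522) and -0.026 (adjusted p 0.358), without vehicle array 1 they were -0.15 and -0.13, and without adenosine array 2 that of the EGFR list was -0.049 (adjusted p 0.220). Over 13 alternatives the adjusted p ran from 7.63e-06 to 0.907 for the TGF-beta list and from 3.94e-04 to 0.859 for the EGFR list.

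**Figure D3:**
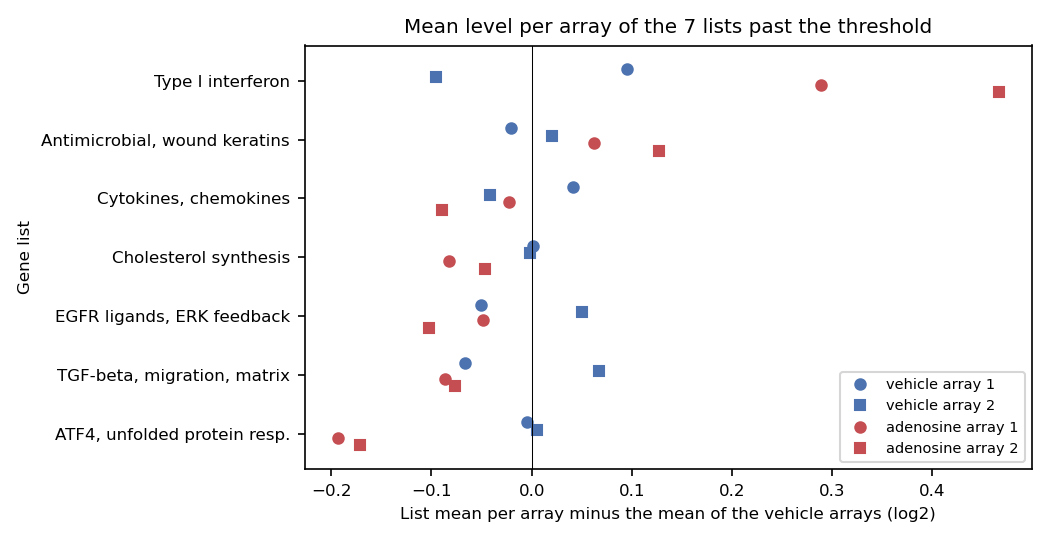
Mean log2 level of each of the 7 lists past camera's threshold, per array, minus the mean of the vehicle arrays; blue is vehicle, red adenosine, circles array 1 and squares array 2. Vehicle array 2 lies highest of the 4 arrays for the TGF-beta and EGFR lists. For the ATF4 list both adenosine arrays (11.10 and 11.12) lie below both vehicle arrays (11.29 and 11.30). The same holds for cholesterol synthesis (11.42 and 11.46 against 11.51 and 11.50) and, narrowly, for the TGF-beta list (11.55 and 11.56 against 11.57 and 11.70).

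Cholesterol synthesis genes had a small negative shift, with 14 of 17 members below 0 and a mean of -0.065. INSIG1, a sterol sensor of the endoplasmic reticulum, had a difference of -0.16 and the mevalonate pathway enzyme MVD one of -0.18, which was -0.10 without adenosine array 2. camera's adjusted p was 0.00736, and the adjusted p = 0.762 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone. The call was lost without vehicle array 1 (adjusted p 0.0534, mean -0.063) and without adenosine array 1 (adjusted p 0.198, mean -0.047), and over 13 alternatives the adjusted p ran from 0.00158 to 0.762.

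Antimicrobial and wound keratin genes had a mean difference of 0.095, with 9 of 13 members positive. SERPINB4, a protease inhibitor whose sequence is close to that of SERPINB3, had a fold of 1.35, while SERPINB3 itself, named after its values were seen, was at 13.53 with vehicle and 13.54 with adenosine, and the beta-defensin DEFB1 had a fold of 1.26. camera's adjusted p was 0.0439, and the adjusted p = 0.859 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone. The call was lost without vehicle array 1 (adjusted p 0.430), without adenosine array 2 (adjusted p 0.221, mean 0.062) and with arrays centred on their medians (adjusted p 0.0506), and over 13 alternatives the adjusted p ran from 0.00474 to 0.859.

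The 3 lists of epidermal layers did not pass. Early differentiation genes had a mean difference of 0.15 over 11 members (camera adjusted p 0.109), with LY6D passing adjusted over the list alone. KRT1, the suprabasal keratin, was at 11.20 and 11.14 on the vehicle arrays, 11.19 on adenosine array 1 and 11.95 on adenosine array 2, the array with the higher beta-actin 3' to 5' difference. Without adenosine array 1 the list's mean was 0.28 (adjusted p 4.61e-05) and without adenosine array 2 it was 0.015 (adjusted p 0.894), the range of adjusted p over 13 alternatives being 4.61e-05 to 0.907. Cornified envelope genes had a mean of -0.050 over 19 members (adjusted p 0.193), with FLG, the precursor of filaggrin, at 12.20 with vehicle and 11.93 with adenosine, and SPRR2B, a small proline-rich protein with near-identical relatives, at 14.46 and 14.32. Without vehicle array 2 their differences went from -0.27 to -0.16 for FLG and from -0.14 to -0.091 for SPRR2B. The cornified list was at -0.14 without vehicle array 1 (adjusted p 2.85e-04), -0.097 without adenosine array 2 (adjusted p 0.0168) and 0.041 without vehicle array 2 (adjusted p 0.358), with adjusted p up to 0.963 over 13 alternatives. Basal and hemidesmosome genes had a mean of -0.034 over 12 members (adjusted p 0.324), with differences of 0.18 for COL7A1, the anchoring fibril collagen (0.11 without vehicle array 1), and -0.11 for the hyaluronan receptor CD44, of whose 8 probe sets 6 were negative.

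Genes of adenosine handling were not called as a list (21 members, mean -0.0034, camera adjusted p 0.766). ADORA2B, an A2 receptor gene, was at 11.24 ± 0.12 with vehicle and 11.25 ± 0.030 with adenosine (SD, n = 2). ADORA1 was at 8.64 and 8.66, with its other probe set at a difference of -0.10, and ADORA3 at 7.18 and 7.13. ADORA2A is not analysed here. The ectonucleotidase NT5E (CD73), which forms adenosine from AMP, had a difference of -0.14, and ENTPD2 one of 0.14, which was 0.062 without adenosine array 2. Targets of cAMP and CREB, the pathway that A2 adenosine receptors activate, had a mean difference of 0.045 over 24 members (camera adjusted p 0.239), and fry's mixed test gave an adjusted p of 0.0339. Adjusted over the list alone, 3 members passed, all positive: ID1, an inhibitor of basic helix-loop-helix factors (fold 1.31), the kinase SIK1 (fold 1.24) and RGS2, a regulator of G protein signalling (0.36, named after its values were seen). Without vehicle array 1 the list's mean was -0.020 (adjusted p 0.607) and without vehicle array 2 it was 0.11 (adjusted p 0.00231), the range of adjusted p over 13 alternatives being 0.00231 to 0.907.

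No shift was called for cell cycle or other stress lists. The camera adjusted p was 0.324 for G1/S and replication genes (21 members, mean 0.044) and 0.598 for G2/M genes (25 members, mean -0.011). PCNA, the replication clamp, had a difference of 0.15 and the cyclin CCNE2 one of 0.24, with -0.063 on the other probe set of CCNE2. Without vehicle array 2 the differences of PCNA and CCNE2 were 0.0022 and 0.0066, and without vehicle array 1 they were 0.30 and 0.47. The mitotic genes CENPE and BUB1 had -0.22 and -0.15, although 3 of the 5 probe sets of BUB1 went the other way. The G1/S mean was 0.14 (adjusted p 1.06e-04) without vehicle array 1 and -0.053 (adjusted p 0.0482) without vehicle array 2, and the G2/M mean was 0.056 (adjusted p 0.127) and -0.078 (adjusted p 0.00231), so the direction of both depended on which vehicle array was kept. The adjusted p of each reached 0.963 over 13 alternatives. The adjusted p was 0.266 for NRF2 targets (15 members), 0.584 for p53 targets (14 members; SESN1 0.23, GDF15 0.22 and 0.020 on its other probe set), 0.875 for hypoxia and glycolysis genes (19 members; the aldolase ALDOC 0.26, VEGFA -0.12, of whose 4 probe sets 3 were negative) and 0.875 for heat shock genes (10 members; HSPB1 0.19, HSPA4L 0.18). Single arrays moved several of these genes: HSPB1 was at 0.080 without adenosine array 2, VEGFA at -0.080 without adenosine array 1, HSPA4L at 0.10 without vehicle array 2 and GDF15 at 0.13 without vehicle array 1. Of the NRF2 list, 3 members passed adjusted over the list alone, SLC7A11 with a negative difference and the aldo-keto reductases AKR1B10 and AKR1C3 with positive ones (AKR1C3 0.35, named after its values were seen). fry's mixed test gave that list an adjusted p of 0.0339. For the hypoxia and heat shock lists the mean was positive (0.014 and 0.024) and the median below 0.

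Markers of other cell types were not called in either direction. Melanocyte markers had a mean difference of 0.015 (11 members, camera adjusted p 0.886, where camera's direction was down), fibroblast markers 0.021 (12 members, adjusted p 0.875, and 0.0080 to 0.034 leaving out each array) and leukocyte and Langerhans cell markers 0.024 (12 members, adjusted p 0.766). Of fibroblast genes, COL1A2, a collagen gene, was at -0.22 on its brightest probe set and 0.027 on the other, and POSTN at -0.31 and -0.057 on the other, its brightest being at -0.16 without vehicle array 2. MITF and TYR, of melanocytes, were at 0.17 and -0.13, and LYZ and TYROBP, of myeloid cells, at 0.22 and 0.11 from vehicle levels of 4.08 and 5.69. LYZ was at 0.027 without adenosine array 2, MITF at 0.062 without adenosine array 1 and TYR at -0.080 without vehicle array 1.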

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

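All settings here were chosen in advance except the removal of genes shared between lists (7 lists called, as in the report), a test chosen only after the data were seen. No alternative gave a gene an adjusted p under 0.05 by limma: the count was 0 in each, single probe sets and a threshold of 0.10 included, leaving out each array gave 0 to 0, and the smallest adjusted p ran from 0.112 (with an intensity trend) to 1. At an unadjusted p under 0.05 the count was 630, and 382 without vehicle array 2 to 905 without adenosine array 1. Of lists, 7 were called, 0 with camera's estimated correlation and 0 with fry, 6 to 10 with other settings and 5 to 8 leaving out each array. With the title number as a replicate block there were 0 genes and 6 lists, the antimicrobial list being lost (adjusted p 0.0725). The numbers were not taken as pairs, and the labels leave open what they mark: deviations of same-numbered arrays from their group means had a correlation of 0.0692 across genes, with only 2 pairs. The series value table moves nothing, since it holds the same values.

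The mean of a gene's probe sets called the NF-kB, cAMP and early differentiation lists (adjusted p 0.0122, 0.0482 and 0.0160), as did leaving out dim genes (0.00493, 0.00546 and 0.00474). Signs turned only for results that were not called. Leaving out each array gave ranges of -0.053 to 0.14 (G1/S), -0.078 to 0.056 (G2/M), -0.058 to 0.0090 (NRF2), -0.018 to 0.011 (adenosine handling), -0.072 to 0.0050 (basal), -0.020 to 0.11 (cAMP), -0.14 to 0.041 (cornified), -0.0064 to 0.054 (heat shock), -0.0098 to 0.037 (hypoxia), -0.054 to 0.10 (leukocyte), -0.071 to 0.10 (melanocyte) and -0.0066 to 0.074 (p53). For the receptors they were -0.087 to 0.13 (ADORA1), -0.075 to 0.092 (ADORA2B) and -0.13 to 0.041 (ADORA3). The NRF2 mean was 0.014 without SLC7A11, which another list holds, hypoxia -0.0038 without dim genes, melanocyte -0.0078 after quantile normalization again, and ADORA1 -0.039 as the mean of its probe sets. The cause was not tested. The arrays' signal over background is not analysed here, so how far it limits dim genes is open.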

Other observations

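Of the tests below, the lists of other gene groups and the comparison with matched random lists were set down before their results were seen, though after those of the report; the tests of the spread between arrays, of adenosine array 2 and of vehicle array 2 were chosen only after the result was seen. Genes for chaperones and degradation factors of the endoplasmic reticulum that no list of the report held were lower with adenosine in 16 of 18 cases, with a mean log2 difference of -0.16. Genes named here were chosen after their values were seen, among those of smallest p in each list. The lower chaperone genes included CRELD2 (fold 0.790), the protein disulfide isomerases PDIA4 (0.781) and PDIA3 (0.839), and the chaperone CALR (0.841). camera's adjusted p over the 7 added lists was 7.57e-10 (adjusted p = 0.157 with an estimated correlation). fry's adjusted p was 0.0423, also over these 7 lists alone, which were drawn up after the report's results. Its unadjusted fry p of 0.00605 was close to the 0.00692 of the ATF4 list, which did not pass fry in the report (adjusted p 0.152). Whether the chaperone genes would pass fry with all lists counted together was not tested. Leaving out each array gave means from -0.18 to -0.15 for these genes. Other ATF4 and amino acid genes had a mean of -0.072, with 13 of 17 negative (adjusted p 0.0111; adjusted p = 0.258 with an estimated correlation, and 0.128 by fry), such as CBS (fold 0.779) and PYCR1 (0.887), but NUPR1 had a fold of 1.13 and the call was lost without vehicle array 1 (adjusted p 0.0840). Aminoacyl tRNA synthetase genes had a mean of -0.045 and a median of -0.017, with 11 of 15 negative (adjusted p 0.0432; adjusted p = 0.258 with an estimated correlation, and 0.228 by fry), a call that held only without vehicle array 1 (adjusted p 0.0309) among the arrays left out. It was lost without vehicle array 2 (mean -0.027), adenosine array 1 (mean -0.037) and adenosine array 2 (mean -0.053). The mean was -0.064 without vehicle array 1.

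All 30 measured genes of oxidative phosphorylation had a positive difference, with a mean of 0.094 (camera adjusted p 1.81e-05; adjusted p = 0.484 with an estimated correlation, and 0.310 by fry). NDUFA2, of complex I, had a fold of 1.16 and COX5B, of complex IV, 1.14. Vehicle array 2 was the lowest, with a list mean of 12.74 against 12.85, 12.89 and 12.88 on vehicle array 1 and the adenosine arrays, and without it the mean difference was 0.038 (adjusted p 0.142). Ribosomal protein genes were not called (mean 0.030 over 33 genes, adjusted p 0.143), though their mean was 0.061 without vehicle array 1 (adjusted p 0.0158) and -4.57e-04 without vehicle array 2 (adjusted p 0.802), nor were genes of MHC class I presentation (mean 0.041 over 14 genes, adjusted p 0.257; 0.069 without vehicle array 1 and 0.012 without vehicle array 2).

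The first pattern is the higher type I interferon list. Interferon-induced genes outside the list were also higher in 23 of 27 cases, with a mean of 0.12. camera's adjusted p was 2.15e-05 (adjusted p = 0.258 with an estimated correlation), and fry's adjusted p was 0.215. The mean was 0.071 without vehicle array 2 and 0.16 without vehicle array 1. These genes were read on the same arrays as the list, so they cannot tell an effect of adenosine from a difference between arrays. The signal level of the genes is argued against, since the list's mean lay above 100% of 10000 random lists matched on expression. Without adenosine array 2 the mean difference was 0.29, against 0.38 with it. This argues against that array's RNA quality as the whole cause, but the array can add to the shift. The list mean was 8.32 on adenosine array 1, against 8.12 and 7.93 on the vehicle arrays. The spread between arrays of the same group stays open: the vehicle arrays differed by 0.19, and fry's adjusted p was 0.551. An effect of adenosine and a difference between arrays unrelated to it both stay open.

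The second pattern is the lower ATF4 and unfolded protein response list, with the endoplasmic reticulum chaperones above. Those chaperones were read on the same arrays, so they cannot tell an effect of adenosine from a difference between arrays. The list's mean lay above 0% of 10000 matched random lists, which argues against signal level. It was -0.19 without adenosine array 2, which argues against that array's RNA quality. The spread between arrays was small, at 0.010 between the vehicle and 0.022 between the adenosine arrays, but fry's adjusted p over the 22 lists was 0.152, so it is not excluded. An effect of adenosine and a difference between arrays unrelated to it both stay open here too.

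The third pattern is the lower TGF-beta and EGFR lists. Signal level is argued against, since their means lay above 0.01% and 0.04% of matched random lists. Neither list was called without vehicle array 2, with means of -0.015 and -0.026, and the EGFR list was also not called without adenosine array 2 (mean -0.049, adjusted p 0.220). These values prompted the test, so they do not show that vehicle array 2 is the cause, which stays open.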
